A study of Danio rerio with 8 samples.

How the data were processed

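RNA from whole zebrafish (Danio rerio) embryos was compared between 3 groups kept for 72 h in control medium (3 samples), high glucose (3 samples) or high salt (2 samples). The concentrations of glucose and salt were not given in the sources used here. Nothing in the labels said that samples of a group came from separate clutches or dishes, so the p-values measured only the spread between these samples, which may be technical.

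The deposited values were raw read counts per gene, whole numbers in 1 table of 31953 genes and 8 libraries. Per the submitters' processing notes, the tools behind the series included HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 and edgeR 3.22.5, with the zebrafish genome build GRCz11; their order and settings were not given in the sources used here. The labels' extraction protocol described hybridization to Illumina arrays, whereas the series type, the listed tools and the whole-number values were those of sequencing counts, and the values were treated as counts. Whether reads were counted by strand was not given, so a gene could not be told apart from an overlapping antisense partner. How reads shared by near-identical gene copies were counted was not given either, and values of tandem copies and multigene families (taurine transporter copies, crystallins, numbered copies such as apoda.2 and ptgdsb.2) are uncertain to that extent. Coordinates are those of the deposited table and were not checked against a genome.

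The table's columns were matched to groups by their names. They carried no replicate number but a suffix, 1m, 2f or 2m (1m and 2m for salt), whose meaning was not stated; libraries are named here by group and suffix. Gene symbols came from the table, and 1081 clone-style names were replaced through a table of gene identifiers and symbols that held 26121 of the 31953 identifiers. Of all genes, 4932 had no count in any library. Library totals ran from 14.65 M counts (high salt 1m) to 17.32 M counts (high glucose 1m), so that 3 counts corresponded to between 0.173 and 0.205 CPM (counts scaled to a common library total). The 7 pairs of libraries within a group differed by 16.7 to 88.4 times the sampling noise (chi-square per degree of freedom), so no library was taken for a duplicate of another.

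Genes were tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) after TMM scaling (factors from 0.891 for high salt 2m to 1.047 for control 2m) and filterByExpr by group, which left 20562 genes. All 8 libraries entered 1 fit with 5 residual degrees of freedom and a median biological coefficient of variation of 0.28 over genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are log2 values with standard errors taken from the fold change and its F statistic. Levels are CPM over TMM-scaled totals, with SD and n. Principal components were computed on log2 CPM with a prior count of 2 over 18419 genes with a mean of at least 1 CPM.

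Gene lists written before the data were examined (49, of which 48 had at least 5 tested members) covered glucose handling, lipids, stress responses, osmotic and hormonal regulation and markers of embryonic cell types. They were tested two-sided with limma's camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Single genes to be named were fixed by rule before the data were examined. They were the 8 largest rises and falls past the threshold (5 and 5 for glucose against salt) with an ordinary symbol, a mean of at least 1 CPM and no overlap between groups; up to 4 members past the gene test for each list past its threshold; a fixed set of genes of glucose and salt physiology whatever their value; and the 5 genes with the lowest p where none passed. Of that set, slc6a6b and isyna1 were not found in the table by symbol and have no value under these names. The table held a taurine transporter gene beside slc6a6a under a different name, and whether it is slc6a6b was not checked. That gene was tested like all others and is reported with the salt results.

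The method was tested on simulated counts for the 20562 genes with 200 of them changed. The changed genes were drawn from those above a minimum mean CPM, and each gene was simulated independently of the others. For glucose against control it recovered 21.69% of 2-fold, 89.09% of 4-fold and 96.77% of 8-fold changes, with 7 unchanged genes called. For salt against control the values were 6.154%, 86.67% and 98.33%, with 8 unchanged genes called. The simulated changed list was recovered in both, and 1 and 0 of 40 unchanged lists were called by camera at the preset correlation. With independent genes this cannot show how often camera calls lists whose genes vary together. On the real libraries, splits that mixed control and glucose gave 9 to 20 lists.

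After the column names had been seen, the suffix was checked as a pairing: deviations from the group means correlated between libraries of the same suffix at 0.52, 0.16 and 0.51 for control with glucose, 0.40 and 0.37 for control with salt and 0.43 and 0.41 for glucose with salt, across genes. Deviations cancel within a group, and those of the 2 salt libraries are equal and opposite. The values with salt are therefore not separate checks of a pairing. Control 2f was not specific to its own suffix. It correlated at 0.18 with glucose 2m and at 0.22 with salt 2m, against 0.16 with glucose 2f. Every value of the same suffix was above 0.1, so a fit with the suffix as a block (3 residual degrees of freedom, coefficient of variation 0.221) is reported wherever it changes a call or moves a count by more than 1.5 times. Other alternatives fixed beforehand were DESeq2's size factors, no scaling beyond library size, no filter on low counts, a filter at 1 CPM in 3 libraries, a threshold of 0.01, a minimum of 2-fold, a fit of only the 2 groups compared, DESeq2 1.42.0, limma voom with quality weights, and the omission of each library in turn. Omitting a salt library left 1 salt library, which was then assumed to vary like the other groups. The tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.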

Results

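Bulk RNA-seq counts were analysed from whole zebrafish embryos kept for 72 h in control medium (n = 3), high glucose (n = 3) or high salt (n = 2). The comparisons address how raised glucose and raised salt alter transcript levels during embryonic development. Total counts were 16.03 M, 15.83 M and 16.44 M in control 1m, 2f and 2m, 17.32 M, 15.33 M and 15.72 M in glucose 1m, 2f and 2m, and 14.65 M and 14.88 M in salt 1m and 2m. The 10 most abundant genes took 6.48% to 8.54% of the counts, and mitochondrially encoded genes took 2.23% (salt 2m) to 5.39% (control 2m).

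By correlation salt 2m and control 1m stood apart, with r of at most 0.936 and 0.935 to any other library. Salt 1m correlated more highly with glucose 1m (0.954) and control 2f (0.942) than with salt 2m (0.936). The other control libraries and the glucose libraries overlapped. Control 2m correlated with glucose 2f (r = 0.977) and glucose 2m (0.975) at least as highly as with control 2f (0.974). The first principal component (39.3% of the variance) placed salt 2m at 108.9 and salt 1m at 29.7, above the other 6 libraries, which lay between -57.1 and -4.8. On the second component (33.1%), control 1m (77.4) and salt 1m (50.4) lay at the top and glucose 2m (-58.6) at the bottom, and within each group the 1m library scored highest.

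**Figure D1:**
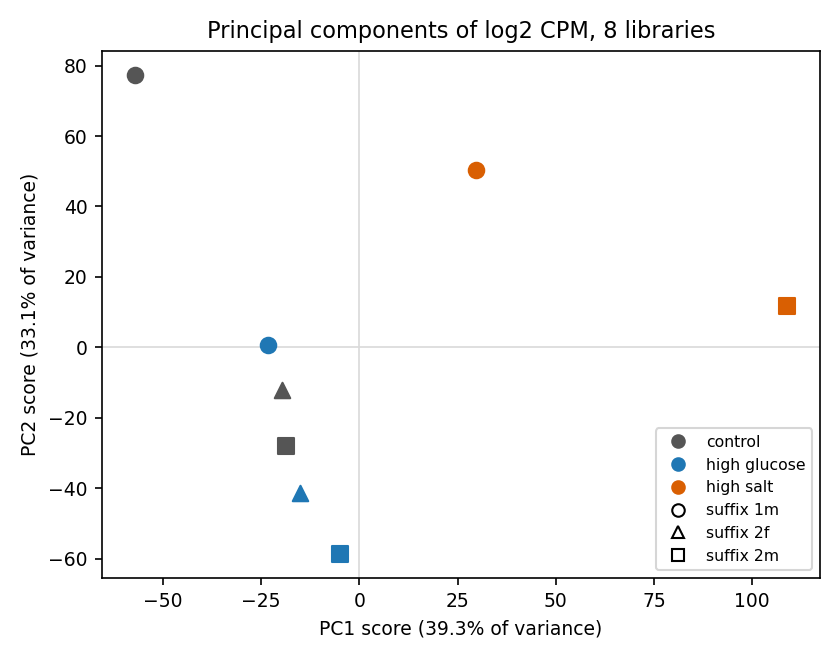
Scores of the 8 libraries on the first 2 principal components of log2 CPM (axes in score units, with the percent of variance), coloured by group and shaped by column suffix. The salt libraries lie at 29.7 and 108.9 on the first component and all others below 0.

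High glucose was compared with control to ask which transcripts respond to raised glucose. Transcripts of the p53 pathway stood lower in glucose as a group, with a median log2 fold change of -0.60 over 20 members and 17 members below 0. Examples, chosen after their values were seen, were the initiator caspase gene casp8 (-1.84 ± 0.26), the cell cycle inhibitor gene cdkn1a (-1.86 ± 0.30) and mdm2 (-1.06 ± 0.19), which encodes a ubiquitin ligase for p53 (log2 ± SE, n = 3 and 3). Lens transcripts stood higher, with a median of 1.17 and 40 of 40 members above 0. Among them, again chosen afterwards, were the crystallin gene cryba1l2 (1.65 ± 0.76) and bfsp2 (2.36 ± 1.07), which encodes a filament protein of lens fibre cells. By camera at the preset correlation, adjusted p was 3.7e-07 for the p53 list and 1.07e-07 for the lens list, and adjusted p = 0.64 with an estimated correlation for both.

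Over all genes, no member of either list passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; adjusted over the list alone, 7 p53 members fell and 0 lens members rose. With the suffix as a block, 2 p53 members fell over all genes and 8 adjusted over the list alone, while 4 lens members rose over all genes and 33 adjusted over the list alone. The lens list also separated libraries of the same treatment. Its median was 2.38 higher in suffix 2 than in suffix 1m libraries with group as a term in the model (31 members higher), whereas the p53 list differed by 0.07 between suffixes, with 2 members higher. That value averaged groups that went opposite ways: the p53 median of salt 2m over salt 1m was 0.75 (17 of 20 members higher), and control 2f and 2m stood -0.34 and -0.37 from control 1m.

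**Figure D2:**
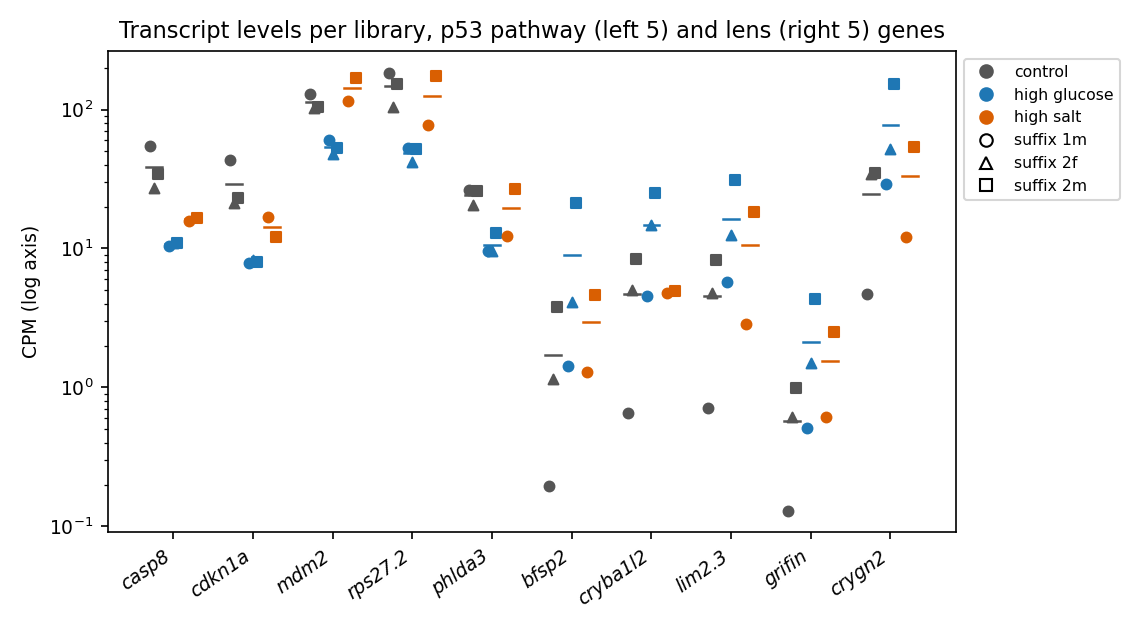
CPM per library on a log axis for 5 p53 pathway genes and 5 lens genes with the lowest unadjusted p in their lists, with points shaped by column suffix and short bars at the group means. In glucose, cdkn1a averaged 7.996 CPM against 29.0 in controls, and the lens genes were lowest in the 1m library of each group, control 1m most of all.

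Of 48 lists, 21 passed the threshold in this comparison, 12 higher and 9 lower in glucose, at the preset correlation. With an estimated correlation none passed (0 with an unadjusted p below 0.05; adjusted p = 0.64 to 0.75 with an estimated correlation across the 21), and none by fry (2 with an unadjusted p below 0.05). The 45 genes of the cell cycle list had a median of 0.35 (40 above 0, adjusted p = 3.79e-07, and adjusted p = 0.64 with an estimated correlation). Pigment cell genes had a median of 0.49 (30 of 33 above 0, adjusted p = 2.57e-06) and neuronal genes one of 0.41 (44 of 51 above 0, adjusted p = 9.41e-05), with adjusted p = 0.64 and adjusted p = 0.67 with an estimated correlation. Glutathione and NRF2 response genes, which include gclc for the rate-limiting step of glutathione synthesis (-1.09 ± 0.32) and gsr for glutathione reductase (-0.77 ± 0.25), had a median of -0.55 with 5 of 28 above 0 (adjusted p = 6.36e-07). Unfolded protein response genes, among them the chaperone gene hspa5 (-0.55 ± 0.24), had a median of -0.29 with 1 of 24 above 0 (adjusted p = 1.74e-04). For both of these lists adjusted p = 0.64 with an estimated correlation. Between suffixes, suffix 2 over 1m, the neuronal list (median 0.86), the pigment list (0.26) and the unfolded protein response (-0.28) moved the same way as with glucose by camera at the preset correlation (adjusted p = 2.16e-15, 0.0031 and 0.0031, and adjusted p = 0.63 with an estimated correlation).

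These 5 lists and the p53 and lens lists, 7 of the 21, passed in each of the 8 fits that left out 1 library. The other 14 lost the threshold at least once. Higher in glucose among these were skeletal muscle (median 0.42), cartilage and bone (0.31), complement and acute phase (0.43), liver (0.19), macrophages and neutrophils (0.34), lipoproteins and yolk lipid transport (0.14), red blood cells (0.35) and endothelium (0.22). Lower were the amino acid stress response (-0.21), mitochondrially encoded genes (-0.27), heat shock proteins (-0.44), sterol synthesis (-0.32), epidermis and keratins (-0.17) and proteasome subunits (-0.15). Of these 14, skeletal muscle (0.55), cartilage and bone (0.52), macrophages and neutrophils (0.50), complement and acute phase (0.45), endothelium (0.26), heat shock proteins (-0.44) and proteasome subunits (-0.18) also moved the same way from suffix 1m to suffix 2. Red blood cells (-0.34) moved the opposite way (over these 8 lists adjusted p = 1.44e-04 to 0.045, and adjusted p = 0.63 to 0.68 with an estimated correlation). Adjusted over the list alone, 1 member each of complement and acute phase and of macrophages and neutrophils fell, against the direction of its list, and apart from these and the p53 members none passed. With the suffix as a block, red blood cells, endothelium (adjusted p = 0.052) and epidermis and keratins no longer passed, and fibroblast matrix did (adjusted p = 0.0092, and adjusted p = 0.73 with an estimated correlation in that fit). Without control 2f the red blood cell list turned downward (adjusted p = 0.92), and without control 1m the proteasome list turned upward (adjusted p = 0.96). Of the 21 lists, 13 kept their call without control 1m, 14 without control 2f, 19 without control 2m, 18 without glucose 1m, 17 without glucose 2f, 13 without glucose 2m and 13 without both control 1m and salt 2m.

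No single gene differed between glucose and control by edgeR's quasi-likelihood test (0 of 20562, lowest adjusted p 0.087). An unadjusted p below 0.05 was reached by 1227 genes where chance gives 1028. A split that mixed control and glucose libraries gave 2006 such genes, so this count does not set the real grouping apart. DESeq2 called 88 genes, limma voom 31 and edgeR without a count filter 16, each of them lower in glucose. The lowest p belonged to lct (chromosome 9, 46588054 to 46595324), rgra (a retinal G protein-coupled receptor), ptgdsb.2 (a prostaglandin D synthase copy), tnfrsf11b (osteoprotegerin) and apoda.2 (apolipoprotein D family, chromosome 2, 37225004 to 37233532). Levels of lct were 17.1 ± 5.2 CPM in controls and 1.24 ± 0.39 CPM in glucose (SD, n = 3 each), a log2 fold change of -3.77 ± 0.41. Those of apoda.2 were 3087 ± 2159 and 86.2 ± 38.9 CPM (-5.16 ± 0.69), with 5565 CPM in control 1m. The log2 fold changes of rgra, ptgdsb.2 and tnfrsf11b were -2.06 ± 0.24, -2.07 ± 0.26 and -3.29 ± 0.43. These genes were also low in salt (n = 2), with lct at 1.47 CPM, rgra at 8.85 against 25.3 CPM in controls, ptgdsb.2 at 372 against 1162, tnfrsf11b at 6.63 against 28.5 and apoda.2 at 437. In salt the first 4 fell (adjusted p = 0.0082, 0.021, 0.020 and 0.038), apoda.2 did not pass (0.054), and none of the 5 differed between glucose and salt. The 5 genes were picked for the lowest p against the same 3 controls. Their low levels in salt are therefore not independent support for a shared fall.

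With the suffix as a block, 36 genes passed, 4 higher and 32 lower in glucose, and these 5 were among the lower ones (adjusted p = 0.0039 for tnfrsf11b and 0.0083 for the others). The 8 largest falls among ordinary symbols in that fit were apoda.2 (-4.92), cd74b (-3.89), which encodes the invariant chain of antigen presentation, lct (-3.78), the opsin gene opn5 (-3.54; it also fell in salt, adjusted p = 0.022), tnfrsf11b (-3.41), the transporter gene abcg2b (-2.99), the coagulation factor gene f10 (-2.93) and the glycine receptor subunit gene glrba (-2.85). The fall of opn5 in salt was measured against the same controls. The rule for naming genes was extended to this fit afterwards. Without the block, adjusted p by edgeR's quasi-likelihood test was 0.17 for cd74b, 0.76 for abcg2b, 0.53 for f10 and 0.73 for glrba. Each of these genes was highest in control 1m, f10 at 2522 CPM against 572 and 371 CPM in control 2f and 2m. The 4 rises were the lens genes cryba2a (1.41), lim2.4 (1.499), crygm2d20 (1.78) and lim2.3 (1.97), named after their values were seen. Without control 1m and salt 2m, which stood apart on the principal components, 20 genes were lower and none higher.

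Genes of glucose metabolism fixed beforehand did not pass the test in either fit. The gluconeogenic gene pck1 was at 88.8 ± 76.7 CPM in controls and 28.2 ± 8.74 CPM in glucose (log2 -1.65 ± 0.58, adjusted p = 0.76), with 173.7 CPM in control 2f alone. The glucose-6-phosphatase gene g6pca.1 differed by -1.70 ± 0.76, insulin (ins) by 0.51 ± 0.71, the glucagon gene gcga by 0.20 ± 0.68, the glucose transporter gene slc2a2 by 0.19 ± 0.26, txnipa by -0.07 ± 0.26 and the fatty acid synthase gene fasn by -0.29 ± 0.37. None of the lists of glycolysis, gluconeogenesis and glucose release, and glucose transport and insulin signalling passed (adjusted p = 0.63, 0.81 and 0.28). The glycolysis list had a median of 0.02 and a mean of 0.0099 while its test pointed downward.

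High salt was compared with control to ask which transcripts respond to raised salt. The pair of taurine transporter genes rose most among the genes with an ordinary symbol, a mean of at least 1 CPM and no overlap between groups. Of these, slc6a6a (chromosome 8, 7100518 to 7152381) rose from 3.01 ± 0.64 CPM (SD, n = 3) to 154 ± 155 CPM (n = 2), a log2 change of 5.68 ± 0.72. The other, SLC6A6 (2 of 2), rose by 5.63 ± 0.53. The myo-inositol transporter gene slc5a3b rose by 4.57 ± 0.63 and the amino acid transporter gene slc38a2 by 4.53 ± 0.38, from 46.3 ± 5.16 to 1073 ± 736 CPM. In the opposite direction, miox, whose product breaks down myo-inositol, fell by 4.17 ± 0.79, and the monocarboxylate transporter family genes slc16a9b and slc16a6b fell by 5.98 ± 0.56 and 5.89 ± 0.61.

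**Figure D3:**
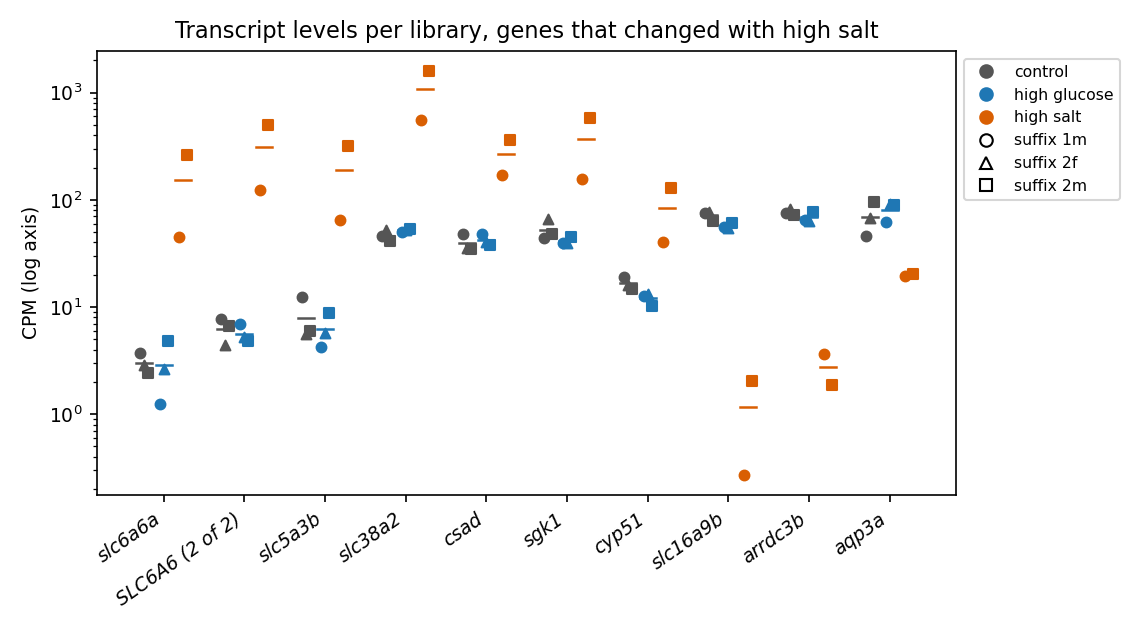
CPM per library on a log axis for 10 genes that changed in high salt, coloured by group and shaped by column suffix, with short bars at the group means. Both salt libraries lie outside the range of the controls for each gene, and slc6a6a was at 45.2 CPM in salt 1m and 264 CPM in salt 2m.

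The osmolyte uptake and synthesis list passed as a group (20 members, median 0.30, mean 0.96, 12 above 0, adjusted p = 0.029, and adjusted p = 0.98 with an estimated correlation; 0.060 with the suffix as a block, 0.13 without salt 2m, 0.074 without both control 1m and salt 2m). Of its members 6 rose and none fell over all genes, and 7 rose adjusted over the list alone. They included slc6a6a, slc5a3b, slc38a2 and csad, a gene of taurine synthesis (2.75 ± 0.30). The kinase gene sgk1 rose by 2.81 ± 0.44 and the water channel gene aqp3a fell by 1.82 ± 0.31. No call was made for the sodium pump gene atp1a1a.4 (0.17 ± 0.28), the calcium channel gene trpv6 (-0.13 ± 0.49), the cotransporter gene slc12a10.2 (-1.13 ± 1.21), prolactin (prl, -1.09 ± 0.63) and cftr (-0.34 ± 0.36).

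Other large rises were those of gjc4a.2 (5.23 ± 0.96), plekhs1 (4.98 ± 0.58), arid5b (4.89 ± 0.86), irg1l (4.69 ± 0.45) and wisp1a (4.66 ± 0.59). In control 1m, 2f and 2m gjc4a.2 was at 0, 0.18 and 0.17 CPM, about the level of 3 counts or below. The size of its rise is therefore uncertain. The gene arid5b was at 2.72 CPM in salt 1m and 31.6 CPM in salt 2m. Other large falls were those of arrdc3b (-4.77 ± 0.31), from 76.4 ± 5.17 to 2.78 ± 1.26 CPM, and of phkg1b (-4.26 ± 0.78), a phosphorylase kinase subunit gene. Still lower counts remained for ftr27, PLEKHS1 (4 of 4) and gchfr, with 1, 2 and 3 counts in both salt libraries together against 132, 140 and 146 in the controls. Their scaled ratios of control to salt were 75.4 (13.3 to 3001), 40 (10.9 to 333) and 27.8 (9.33 to 136), with exact 95% binomial intervals that cover counting error only. The adjusted p of the genes in this paragraph lay between 3.44e-04 (arrdc3b) and 0.022 (phkg1b).

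Sterol synthesis genes rose as a group in salt (24 members, median 0.83, 23 above 0, adjusted p = 1.14e-04, and adjusted p = 0.98 with an estimated correlation; 0.074 without both control 1m and salt 2m). Past the gene test were cyp51 (2.34 ± 0.39), the squalene epoxidase gene sqlea (2.41 ± 0.42) and tm7sf2 (2.85 ± 0.54), and 8 members adjusted over the list alone. Fibroblast matrix genes rose likewise (41 members, median 0.54, adjusted p = 1.14e-04, and adjusted p = 0.98 with an estimated correlation; 0.97 without both control 1m and salt 2m). Of them 5 rose over all genes and 9 adjusted over the list alone, including col5a3a (1.41 ± 0.21), ogn (1.36 ± 0.27), the fibronectin gene fn1a (1.17 ± 0.28) and thbs4b (1.02 ± 0.20). Of the inflammation list (25 members, median 0.41, adjusted p = 0.037, and adjusted p = 0.98 with an estimated correlation; 0.32 without both control 1m and salt 2m), 3 rose over all genes and 4 adjusted over the list alone. These 3 were the chemokine gene ccl19a.1 (2.77 ± 0.61) and 2 genes of NF-kB inhibitors, nfkbiab (2.31 ± 0.37) and nfkbiaa (1.99 ± 0.47).

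Ribosomal protein genes had a median of 0.34 with 75 of 84 above 0 (adjusted p = 5.24e-05, and adjusted p = 0.98 with an estimated correlation), and 0 of them passed the gene test over all genes or adjusted over the list alone. Neuronal genes had a median of 0.51 (adjusted p = 0.037, and adjusted p = 0.98 with an estimated correlation), with dpysl5a (1.05 ± 0.22) the 1 member that rose in either adjustment. Without both control 1m and salt 2m the neuronal list passed in the opposite direction, downward (adjusted p = 0.025). Mitochondrially encoded genes had a median of -0.60 (13 members, adjusted p = 0.037, and adjusted p = 0.98 with an estimated correlation; 0.30 without both control 1m and salt 2m). The 1 member past the test over all genes, mt-atp8, rose by 1.18 ± 0.29, and adjusted over the list alone 1 rose and 4 fell. The mitochondrial list no longer passed with the suffix as a block (adjusted p = 0.17), without control 2f (0.080) or 2m (0.069), or with scaling by library size alone (0.057), and the inflammation list did not pass with a stricter count filter (0.12). Glycolysis passed with the block (adjusted p = 0.027, and adjusted p = 0.96 with an estimated correlation in that fit). Mitochondrial counts were lowest in salt 2m, and the fibroblast matrix, neuronal and inflammation lists were also higher in suffix 2 than in suffix 1m libraries (medians 0.56, 0.86 and 0.49). Suffix 2 made up more of the controls (2f and 2m beside 1m) than of salt (2m beside 1m). A suffix difference alike in all groups would therefore lower these lists in salt, and they still passed with the suffix as a block. Without control 1m the inflammation and neuronal lists did not pass (adjusted p = 0.078 and 0.68). Without salt 2m none of the 7 lists passed (0 by camera at the preset correlation, 8 with an unadjusted p below 0.05; the neuronal list turned downward, adjusted p = 0.90), and without salt 1m 11 did. By fry, no list passed in the fit of all libraries (2 with an unadjusted p below 0.05).

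In all, 1101 of 20562 genes changed with salt, 605 higher and 496 lower, and 857 of them by at least 2-fold. Scaling by library size alone gave 400 higher and 504 lower and moved the median log2 fold change of all genes from -0.043 to -0.139. Limma voom gave 490 higher and 135 lower. The suffix block gave 2550 genes (1216 higher, 1334 lower), the 1101 among them. The count depended on single libraries: it was 50 without salt 2m, 2355 without salt 1m, 164 without control 2f, 147 without control 2m, 471 without glucose 1m, 215 without glucose 2f, 343 without glucose 2m and 352 without both control 1m and salt 2m. Of the 32 salt genes named above that passed, 9 passed in each of the 8 fits with 1 library left out: slc6a6a, SLC6A6 (2 of 2), slc38a2, csad, irg1l, plekhs1, slc16a9b, slc16a6b and arrdc3b. The other 23 did not pass without salt 2m (adjusted p = 0.057 for slc5a3b to 0.39). Of the 32 genes 3, 17, 19, 5, 12, 8 and 1 did not pass without control 1m, 2f, 2m, glucose 1m, 2f, 2m and salt 1m respectively. A fit of only the salt and control libraries ended 21 of the 32 calls (adjusted p = 0.050 to 0.15), the fit without both control 1m and salt 2m ended 11 (0.060 to 0.24), and scaling by library size alone ended 2 (0.062 to 0.082). Limma voom ended 12 (0.052 to 0.17), namely arid5b, ftr27, PLEKHS1 (4 of 4), gchfr, phkg1b, miox, tm7sf2, nfkbiaa, mt-atp8, dpysl5a, thbs4b and fn1a.

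High glucose was then compared directly with high salt, which tests whether the treatments differ. The taurine transporter genes SLC6A6 (2 of 2) (-5.78 ± 0.53) and slc6a6a (-5.75 ± 0.72), wisp1a (-5.62 ± 0.63), gjc4a.2 (-5.50 ± 0.98) and slc5a3b (-4.93 ± 0.64) were the named genes lowest in glucose relative to salt. Highest in glucose were slc16a9b (5.65 ± 0.56), slc16a6b (5.51 ± 0.61), ftr27 (5.36 ± 0.88), phkg1b (4.90 ± 0.79) and miox (4.89 ± 0.80), where ftr27 had 87 counts in glucose and 1 in salt, a scaled ratio of 49.2 (8.61 to 1967). In glucose 1m, 2f and 2m gjc4a.2 was at 0.23, 0.06 and 0 CPM, so the size of its difference is uncertain too. In all 1017 genes differed, 390 higher and 627 lower in glucose (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1857 with the suffix as a block (886 higher and 971 lower). The lean toward genes lower in glucose was smaller with the block and with scaling by library size alone (394 higher and 453 lower). That scaling moved the median over all genes from 0.040 to 0.15. The count was 2343 without control 1m, 560 without control 2f, 620 without control 2m, 198 without glucose 1m, 59 without glucose 2f, 72 without glucose 2m, 2094 without salt 1m and 65 without salt 2m. Of the 10 named genes, 4 did not pass without glucose 2m, 6 without glucose 2f and 3 without salt 2m, and with limma voom ftr27 and phkg1b did not (adjusted p = 0.10 to 0.13). Limma voom gave 176 genes higher and 685 lower in glucose.

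Of 48 lists 13 passed, each with adjusted p = 0.99 with an estimated correlation and none by fry (5 with an unadjusted p below 0.05) or by camera with an estimated correlation (0). Sterol synthesis genes were lower in glucose than in salt (median -1.11, 7 members lower over all genes and 15 adjusted over the list alone, adjusted p = 4.80e-07). So were, with values in the same order, heat shock proteins (-0.71, 4 and 6, adjusted p = 0.0094) and the unfolded protein response (-0.47, 2 and 5, adjusted p = 0.0012). These 3 lists passed in each of the 8 fits with 1 library left out. P53 pathway genes were lower as well (-0.86, 4 and 12, adjusted p = 5.87e-04, 0.10 without salt 2m). The remaining lists lower in glucose were ribosomal proteins (-0.28, 0 and 0), fibroblast matrix (-0.30, 3 and 8), the amino acid stress response (-0.55, 3 and 7), inflammation (-0.42, 1 and 4), glutathione and NRF2 response (-0.40, 2 and 7), glycolysis (-0.28, 2 and 7), osmosensing and WNK kinases (-0.48, 2 and 3) and proteasome subunits (-0.25, 0 and 0). Glycolysis, osmosensing and proteasome each also had 1 member higher in glucose in both adjustments, and the heat shock and p53 lists had 1 adjusted over the list alone. Lens genes were higher in glucose (1.42, 39 of 40 above 0, adjusted p = 0.021), with 0 past the gene test in either adjustment and 16 past it over all genes with the suffix as a block. The lens list did not pass without glucose 2m (adjusted p = 0.44), without salt 1m (0.85) or with scaling by library size alone (0.067). The proteasome list did not pass with the suffix as a block (0.12), with scaling by library size alone (0.11), or without glucose 2f (0.062), glucose 2m (0.16) or salt 1m (0.15). With the block, red blood cells passed (adjusted p = 0.0055, and adjusted p = 0.93 with an estimated correlation in that fit). Without glucose 1m, glycolysis, glutathione and NRF2 response, inflammation and osmosensing did not pass (adjusted p = 0.051 to 0.14). Without salt 2m 5 lists passed, 4 of them among the 13 (adjusted p = 0.10 to 0.56 for the other 9), and without both control 1m and salt 2m 6 did, 5 of them among the 13.

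No gene passed against control in both treatments (0 by edgeR's quasi-likelihood test; 1227 and 5318 genes had an unadjusted p below 0.05 in the glucose and the salt comparison), whereas DESeq2 gave 37 such genes and limma voom 5. With the suffix as a block, 1 gene was higher and 23 were lower in both treatments, where independent lists of those sizes would share 0.24 and 2.08. These values leave out the shared controls, and the overlap under the block was not simulated. Fold changes of the 2 comparisons correlated at r = 0.288 across 18419 genes, which are not independent replicates, and 60.9% had the same sign. In 20 simulations of unchanged groups against the same controls, r averaged 0.446 (0.43 to 0.461) and the same-sign share 63.6%. The covariance was 0.103, against a simulated 0.0787 (0.076 to 0.0826). Only the covariance lay above its simulated range. Both r and the same-sign share lay below theirs (lowest simulated share 62.7%), so these measures gave no single answer on a shared response. The 3 control libraries could not be split into parts of 2 libraries each, so part of the excess in covariance may come from the shared controls.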

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

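Of the tests in this part, the counts over other splits of the samples were set before their results were seen, and all the others were chosen after. For the tests on medians, the condition that the bootstrap interval must clear the bound was added after a first run. These intervals, here and in the stage tests below, resampled genes within the libraries compared. They treat genes as independent and hold no spread between libraries, so they do not show whether a difference would recur in other libraries.

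In 104 genes, all 3 glucose libraries lay below and both salt libraries above every control, and the direct comparison of glucose with salt passed the test. The log2 differences of glucose from salt were -2.795 for acer1, -1.799 for ANO9 (2 of 2), -5.619 for wisp1a, -2.339 for ftr86, -3.002 for jund and -1.442 for rhoub, with adjusted p of 0.0015, 0.0035, 0.0040, 0.0040, 0.0040 and 0.0051 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among genes with an ordinary symbol in either order these 6 had the lowest p, and 51 genes passed in the opposite order. Against control, 5 of the 6 passed in salt (adjusted p = 0.0030 for acer1 to 0.0082 for ftr86; 0.053 for rhoub), while in glucose adjusted p lay between 0.49 (rhoub) and 0.85 (jund). Levels of wisp1a were 0.40, 0.31 and 0.19 CPM in glucose 1m, 2f and 2m, against 0.65, 0.67 and 0.47 CPM in the controls. With 3 counts at 0.173 to 0.205 CPM, its place below the controls rests on few reads. Passed or not, glucose lay below every control in 155 of 3603 genes with salt above every control (4.3%) and above in 121 of 3760 with salt below (3.2%). On the same side as salt, glucose lay beyond every control in 596 and 592 genes. The salt effect and the shared controls both shape these counts, and what chance would give under both was not computed, so the number of such genes shows neither an excess nor its absence.

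High salt 2m showed larger fold changes than high salt 1m, with 81.7% of the genes that passed for salt against control further from the controls in 2m. Over the 50 genes that passed without salt 2m, 100% had the same sign in salt 2m and the median ratio of log2 fold changes, 2m over 1m, was 1.12 (95% bootstrap interval 1.05 to 1.35; 34 genes above 1), so the same genes may have responded more in that library. Over these genes the gap of 2m over 1m was -0.06 in controls (-0.16 to 0.10) and -0.09 in glucose, against 0.28 in salt. The genes had passed in a fit whose spread came only from control and glucose libraries, which favours small gaps there. These gaps therefore cannot decide whether the suffixes differ in a way that all groups share. A difference in library size was argued against by a ratio of totals of 1.016. Dose, survival and clutch were not given for single libraries, so a biological and a handling difference stay open.

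The p53 list lower and the lens list higher with glucose were weighed together. Control 1m as the sole source was argued against for both, since the glucose over control medians of the 2f and 2m pairs were -0.51 and -0.52 for p53 and 1.26 and 1.18 for lens, and without it adjusted p by camera at the preset correlation was 1.66e-07 and 0.0092. With all libraries adjusted p = 0.64 with an estimated correlation for both, and no list passed by fry (adjusted p = 0.58 for both). A stage-like difference that also separates suffix 1m from suffix 2 was tested in glucose 2f over glucose 1m, libraries of the same treatment: the p53 median was 0.03 (-0.14 to 0.20), against -0.91 in the 1m pair of glucose over control, while control 2f and 2m stood -0.34 and -0.37 from control 1m and salt 2m stood 0.75 above salt 1m, so no single direction separated the suffixes. The lens median was 1.26 (1.02 to 1.85), as large as its glucose over control pairs in 2f and 2m (2.19 in 1m), so a difference in stage may account for the lens result. A response to glucose stays open for both lists.

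Other splits of the 6 control and glucose libraries were counted for the results of that comparison, and they are too few for a share under 0.05. For genes the count says nothing, because the real split gave 0 and all 10 of the 10 splits into 3 and 3 had to give as many (real 0, highest other 0 by edgeR, while DESeq2 gave 88 and limma voom 31 in the real split). With an unadjusted p below 0.05 edgeR gave 1227 genes in the real split. Splits that mixed control and glucose gave 114 to 2006, so the real split did not give the most. With the suffix as a block, 1 of the 4 splits that part all 3 suffix pairs gave as many, the real one with 36 genes against 0 in the highest other. For lists 1 of the 10 splits gave as many, the real one with 21 against 20 in the highest other, which set control 1m, control 2m and glucose 1m against the rest, so the number of lists alone does not separate the treatment from that grouping.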

How the results depend on the processing

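The fits with the column suffix as a block and with its number as a batch, and the fit without control 1m and salt 2m, were chosen after the column names or the data had been seen, and the other alternatives before. Values that moved are given below, and unless an alternative's construction (fewer libraries, a lower threshold) shows it, the cause was not tested.

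No paired analysis was possible by the titles' replicate numbers because the columns carry none. With the column suffix as a block instead, 36 genes passed for glucose against control, 2550 for salt against control, 1857 for glucose against salt and 24 in both treatments. Under that block trpv6 in salt turned to 0.26, and beyond the calls given with each comparison the block changed no other call among the named genes and lists. With the suffix number alone as a batch the counts were 35, 3907, 3008 and 21, and trpv6 stood at 0.055.

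For glucose against control, where edgeR gave 0 genes, DESeq2 gave 88, limma voom 31, no count filter 16 and the fit without control 1m and salt 2m 20, and in both treatments the counts were 37, 5, 10 and 2. Both scaling alternatives, the stricter filter and each fit without 1 library gave 0 genes for both. For salt against control DESeq2 gave 2676 genes, limma voom 625, a fit of only these groups 72, a threshold of 0.01 91 and the fit without control 1m and salt 2m 352. For glucose against salt DESeq2 gave 2501 and a threshold of 0.01 gave 88. Of the lists, 0 passed in any comparison with an estimated correlation and 0 by fry (21, 7 and 13 with the preset correlation), and 6 passed for glucose against salt without control 1m and salt 2m.

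Leaving out 1 library at a time gave 50 to 2355 genes and 0 to 11 lists for salt against control, and 59 to 2343 genes and 5 to 17 lists for glucose against salt. A salt library left alone was assumed to vary like the other groups. Across these fits txnipa in glucose ran from -0.28 to 0.17, slc2a2 from -0.027 to 0.41 and gcga from -0.55 to 0.63. In salt trpv6 ran from -0.51 to 0.36 and slc12a10.2 from -1.69 to 0.030. None of these 5 genes had passed the test. The adjusted p ran from 7.03e-06 to 0.92 for red blood cells and from 0.0023 to 0.96 for proteasome subunits in glucose, and from 4.46e-05 to 0.90 for neurons in salt, each with a turn of direction at the upper end. Without control 1m and salt 2m, txnipa stood at 0.013 and gcga at -0.033 in glucose, and the neuronal list in salt turned downward (adjusted p = 0.025). With limma voom gcga stood at -0.20.

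Among the other values, 263 of the named genes' alternatives kept direction and side of the threshold for glucose against control, 571 for salt against control and 179 for glucose against salt, and 249, 76 and 152 of the lists' did. Calls ended in 155 and 19 alternatives of named genes for salt against control and glucose against salt, and in 85, 34 and 56 of lists for glucose against control, salt against control and glucose against salt. New calls were made in 50 alternatives of genes for glucose against control.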

Other observations

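The tests of a tailbud gene list were written before their results were seen; the gene families and single genes described here, and the test of library size, were chosen after.

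Genes of 2 families fell in high salt beyond those already named. All 3 linker histone genes tested fell, histh1l by 2.89 ± 0.28, h1f0 by 2.59 ± 0.23 and h1fx by 3.98 ± 0.38 on the log2 scale (± SE, n = 3 and 2), and in glucose they differed from control by 0.06, 0.22 and 0.01 without a call. Of 7 arrestin-domain genes tested, txnipa (-2.15 ± 0.32), arrdc3a (-2.74 ± 0.26) and arrdc3b fell and arrdc1b (0.90 ± 0.22) rose. All 10 kept their direction under each scaling, which is no check, because the scalings moved genes too little to turn changes of this size. By edgeR's quasi-likelihood test arrdc1b did not pass with scaling by library size alone (adjusted p = 0.083). The gene with the lowest p for salt against control was mgea5, which fell by 3.97 and encodes the enzyme that removes O-GlcNAc from proteins (adjusted p = 1.87e-04).

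Libraries of suffix 2 differed from those of suffix 1m within the groups. With group as a term, 1089 genes were higher and 604 lower in suffix 2, and 19 of 48 lists passed by camera at the preset correlation (0 with an estimated correlation). Lens (median 2.38), neuronal (0.86), fibroblast matrix (0.56) and skeletal muscle (0.55) genes were higher in suffix 2. The tailbud gene tbx6 was at 20.8 CPM in control 1m and 0.67 and 0.99 CPM in control 2f and 2m. It was at 5.88 CPM in glucose 1m against 0.38 and 0.50 CPM in glucose 2f and 2m, and at 17.2 CPM in salt 1m against 1.21 CPM in salt 2m.

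An earlier stage of the suffix 1m embryos may underlie this pattern. A list of 27 tailbud and presomitic mesoderm genes, written without the genes already seen, had 23 tested members. Its medians for suffix 2 over 1m were -1.31 in controls, -0.44 in glucose (-0.76 to 0.08) and -0.49 in salt (camera adjusted p = 2.96e-05, and 0.61 with an estimated correlation). The prediction written before asked for a median at or below -0.5 in each group, which glucose and salt both missed. No median lay above -0.25, the bound written before for excluding this explanation, and it was left open. Library size was argued against by a ratio of mean totals of 0.977. What the suffix stands for was not given in the sources used here.

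A later stage of the glucose embryos than of controls of the same suffix was tested with the same list, and could be neither shown nor excluded. The medians of the 3 pairs were -0.75, 0.15 and -0.15, with an interval of -0.43 to 0.44 for the highest (camera adjusted p = 0.050, and 0.71 with an estimated correlation). A first run without the bootstrap interval had excluded this explanation, and adding the interval afterwards turned the verdict to open.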
